A study of Rattus norvegicus with 28 samples.

How the data were processed

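RNA expression was measured in whole brains of rats of the inbred strains BN-Lx/Cub and SHR/OlaIpcv. Per the labels, total RNA was extracted with column kits and made into stranded libraries after removal of ribosomal RNA (Ribo-Zero). Paired-end reads were sequenced on an Illumina HiSeq with 4 libraries per lane. The protocol in the labels speaks of male rats, while the sample labels name females at 3 stages of the estrous cycle and males. The sample labels were used for grouping. Whole brains were used, so each library was taken as a separate animal.

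Per the submitters' processing notes, cutadapt and RSEM were used, with no version given. The aligner settings, the genome build and the annotation are not given in the sources used here. The deposited per-sample files hold expected counts per gene, which are RSEM's estimates in which a read that fits several genes is divided between them, with no normalization. Each file has 32715 rows, made up of 32623 Ensembl gene identifiers and 92 ERCC spike-in RNAs, synthetic transcripts added to the RNA. The authors' gene lengths in the same files were used only as descriptions. The deposited series matrix held the same expected counts, with a largest difference of 0.5, and 2 of the whole-number gene counts differed after rounding. Of all values, 88.2% were already whole numbers.

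The files do not pair identifiers with gene names, and the reference table at hand had no Ensembl identifier in any row, so 0 gene identifiers were matched to a symbol. Genes are therefore given by identifier, with at most 2 higher and 2 lower per comparison. The 40 gene lists fixed before the data were examined (646 entries) matched 0 rows and were not tested. The rule for named genes, fixed before the data were examined, took called genes with a symbol and a mean of at least 1 CPM with the largest change in each direction. It was applied without the symbol, and the genes it listed for each function were not looked up.

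Expected counts were rounded to whole numbers. Spike-in rows were left out of library sizes and tests. Genes were kept by edgeR's filterByExpr with a count minimum of 10 over the 8 strain-by-sex/stage groups, which left 18134 genes. TMM factors scaled the libraries. All 28 libraries entered a single edgeR quasi-likelihood fit (robust), which had a term for each group and a term for the suffix b35 or b37 in the sample description. The meaning of the suffix is not stated in the labels, and it was treated as a possible technical batch. The fit had 19 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Female strain and sex contrasts weighted the 3 stages equally. Standard errors of log2 fold changes were derived from the F statistic and are approximate. A fold against a group with no count in any library was given as a lower bound, from the lowest CPM of the other group and a floor of 3 counts in the library of that group with the highest floor. CPM levels used TMM-scaled library sizes. Principal components used log2 CPM with a prior count of 2.

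Total expected counts ran from 43410563 to 90667238 per library, spike-ins included. The median standard error of the female strain difference was 0.44 on the log2 scale for genes under 1 CPM and 0.079 for genes over 64 CPM. Pairs of libraries of a group were compared by chi-square over the kept genes, only to find copies of a library. The chi-square per degree of freedom was 29.0 to 636 over the 38 pairs, so no pair agreed within sampling noise, as copies of a library would. Of the 14739 gene rows with over 1000 counts in total, 107 had counts identical to those of another row in every library. Such rows share their reads, and their separate levels are uncertain. They include 17 of the genes called between strains and 0 of the genes named in the text. Rows with lower totals were not searched, so more of the called genes may share their reads.

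The calculation was tested on simulated data drawn from the real means, library sizes and dispersions, with 200 changed genes among 18134. Genes were drawn independently of one another, so the simulation lacked the differences that many genes share between libraries of a group (below). Its recovered shares and false calls may therefore not hold for the real libraries. In the simulated comparison of estrus with pre-estrus in BN-Lx, edgeR recovered 17.9% of genes changed 1.5-fold, 44.8% of those changed 2-fold and 75.8% of those changed 4-fold, and 6 of 98 calls were false. DESeq2 recovered 29.9%, 59.7% and 75.8% there, and 31 of 141 calls were false. In the simulated strain comparison in females, edgeR recovered 61.2%, 76.1% and 87.9%. The recovered shares were 4.48%, 28.4% and 57.6% for strain in males, and 8.96%, 37.3% and 80.3% for sex in BN-Lx.

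Alternatives fixed before the data were examined were a fit without the suffix term, the number in the sample description or the replicate number as a block, DESeq2 size factors, DESeq2 itself, no filter on low counts, a filter on a mean of 1 CPM, the series matrix, only the libraries of the groups compared, and leaving out each library in turn. Limma, where named, is limma voom with quality weights per library. Further alternatives were chosen after seeing the data and are named as such with their results. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Permutation tests of single values used 100000 resamples and were two-sided.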

Results

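Gene expression was measured by total RNA sequencing in 28 rat brains, to ask how sex and the stage of the estrous cycle act on brain RNA in different genetic backgrounds. BN-Lx/Cub is a Brown Norway strain and SHR/OlaIpcv is a spontaneously hypertensive strain. Each strain had 12 females, 4 each at pre-estrus, estrus and post-estrus, and 2 males. Both BN-Lx males carry the number 200537 in the sample description, both SHR males 199890, and all SHR pre-estrus females 201066. The meaning of the number is not stated. Each of these numbers also occurs in other groups of its strain, so sex and stage are partly tied to it. Total expected counts averaged 59819485 ± 10130858 per library (SD, n = 28), and ranged from 43410563 in BN-Lx post-estrus replicate 6 to 90667238 in BN-Lx post-estrus replicate 4. Each library detected between 16607 and 20192 genes with at least 1 count. Spike-in RNAs took 1.47% to 6.05% of the counts.

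The first principal component of log2 CPM held 19.97% of the variance and separated all BN-Lx libraries from all SHR libraries. Its mean was 31.5 ± 16.3 in SHR females and -32.9 ± 29.3 in BN-Lx females (SD, n = 12 each, permutation p = 2e-05, adjusted over 6 measures 0.00012). The difference was 79.7 among b35 libraries and 53.1 among b37 libraries. The second component held 16.1% and spread libraries of both strains without separating the stages.

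**Figure D1:**
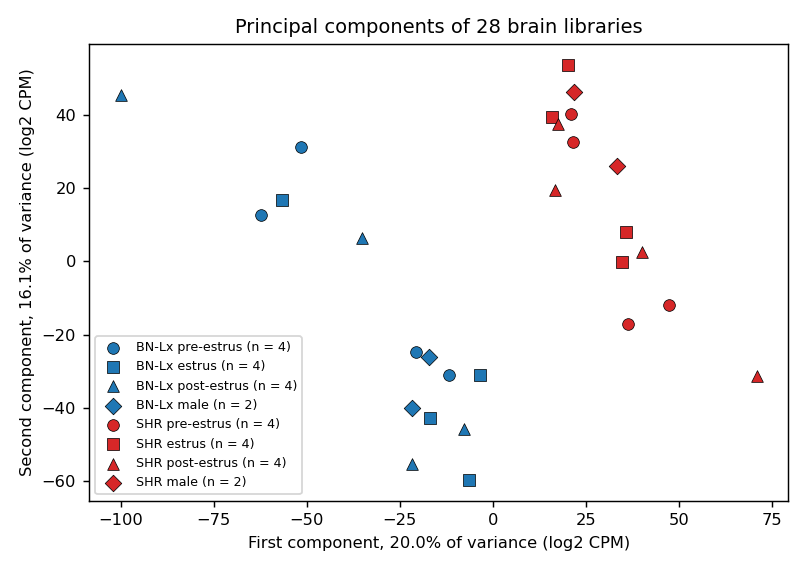
Position of each of the 28 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, with colour for strain and symbol for stage or sex. All BN-Lx libraries lie to the left of all SHR libraries, and symbols of the stages are mixed within each strain.

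A few RNAs took a large part of each library. The most abundant gene held 25.9% ± 5.34 of the gene counts (SD, n = 28), from 13.2% in SHR post-estrus replicate 13 to 35.9% in BN-Lx post-estrus replicate 5. The 8 most abundant genes together held 34.8% to 50.7%. They were matched to no gene name, and a pair of them, of 300 bases each, had identical counts in every library. Whether they include ribosomal RNA left after its removal was not determined. These 8 genes held 41.4% ± 3.08 in SHR females and 46.5% ± 2.48 in BN-Lx females (SD, n = 12 each, permutation p = 0.00014, adjusted 0.00042). The difference was -5.87 percentage points among b35 libraries and -4.54 among b37 libraries. The most abundant gene alone held 23.15% ± 4.4 in SHR females and 28.6% ± 5.62 in BN-Lx females (permutation p = 0.0143, adjusted 0.0286), a difference of -6.96 percentage points among b35 libraries and -3.85 among b37 libraries. Library totals did not differ detectably between the strains (permutation p = 0.621, adjusted 0.621).

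**Figure D2:**
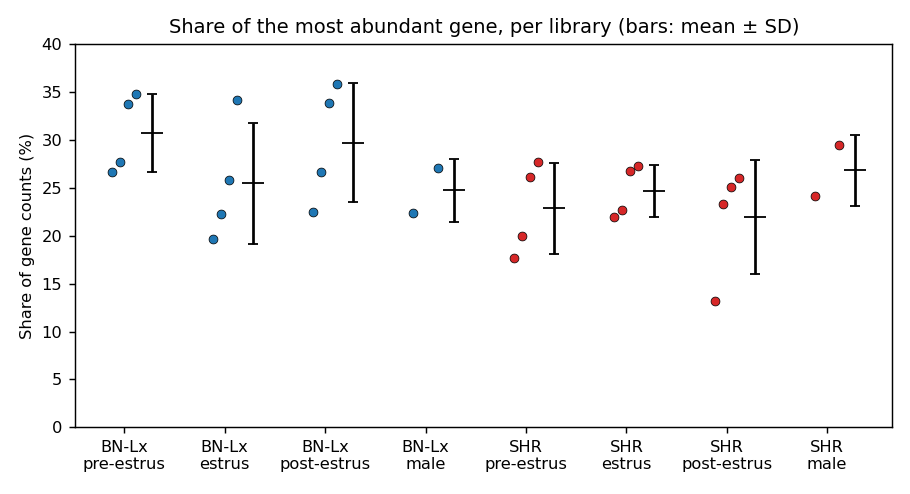
Share of gene counts held by the most abundant gene (y axis, percent) in each library of the 8 groups (x axis), with points for libraries and bars for the mean ± SD. Shares ran from 13.2% to 35.9%, with means of 23.15% in SHR females and 28.6% in BN-Lx females.

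The strain comparison in females asked which genes differed between SHR and BN-Lx brains irrespective of the stage. Of 18134 genes, 1724 were called, 830 higher and 894 lower in SHR. The balance of directions turned in other settings. Higher in SHR were 1229 of 1819 genes with b35 libraries alone, 1318 of 2319 with RNA shares as covariates, 1134 of 2194 with limma voom with quality weights (called limma from here on) and 914 of 1806 without 3 outlying libraries. They were 867 of 1733 without BN-Lx estrus replicate 2, 933 of 1840 without BN-Lx post-estrus replicate 4 and 800 of 1599 without SHR pre-estrus replicate 11. The median size of the change among called genes was 0.57 on the log2 scale, with quartiles of 0.33 and 1.31. A change of more than 2-fold was found for 540 called genes, 229 higher and 311 lower, and more than 4-fold for 278, 113 higher and 165 lower. The 12 SHR and 12 BN-Lx values did not overlap for 283 genes, where chance would give 0.0134.

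The genes with the largest differences were close to absent in one of the strains. ENSRNOG00000055352 reached 140 ± 88 CPM in SHR females and 0.0363 ± 0.04 CPM in BN-Lx females (SD, n = 12 each), a log2 fold change of 11.8 ± 0.51 (SE, adjusted p = 1.5e-13). ENSRNOG00000019050 reached 6.92 ± 2.93 CPM in SHR and 0.00706 ± 0.0202 CPM in BN-Lx, a log2 fold change of 9.96 ± 0.47 (SE, adjusted p = 1.3e-11). In the other direction, ENSRNOG00000028449 had 173 ± 50.9 CPM in BN-Lx and 0.00955 ± 0.0231 CPM in SHR, a log2 fold change of -14.24 ± 0.40 (SE, adjusted p = 4.8e-15). ENSRNOG00000059663 had 11.7 ± 2.36 CPM in BN-Lx females and no count in any of the 12 SHR females, which is at least 111-fold lower in SHR (adjusted p = 2.6e-12). The sizes of these folds depend on few counts. That of ENSRNOG00000019050 was 10.99 without BN-Lx estrus replicate 2, and that of ENSRNOG00000028449 was -15.33 without SHR estrus replicate 6 and -15.14 without SHR post-estrus replicate 13. The lowest and highest counts of ENSRNOG00000028449 were 4861 and 13742 in BN-Lx and 0 and 4 in SHR.

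Called genes were found at all expression levels. They made up 9.72% of 4084 genes under 1 CPM, where the median size of the change among called genes was 2.04 on the log2 scale. They made up 13.1% of 2690 genes at 1 to 4 CPM, and 6.05% of 2032 genes over 64 CPM, where the median size was 0.31. The median standard error fell from 0.44 to 0.079 from the lowest to the highest of these bins. The number of called genes was 1819 with b35 libraries alone, of which 967 were among the 1724, and 478 with b37 libraries alone, of which 466 were.

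The same strain comparison in males, with 2 animals per strain, called 145 genes, 60 higher and 85 lower in SHR. Higher were 481 of 745 with limma, 280 of 471 with RNA shares as covariates and 30 of 55 with b35 libraries alone. All 145 were also called in females, with the same direction. Independent lists would share 2.75 genes higher and 4.19 lower. The lists are not independent, however, since both comparisons used the same error estimate for each gene. ENSRNOG00000055352 was again high in SHR (144 ± 45.3 CPM, SD, n = 2) and at 0.0169 ± 0.024 CPM in BN-Lx males, a log2 fold change of 13.17 ± 1.34 (SE, adjusted p = 4.7e-06). Its counts in the BN-Lx males were 2 and 0, and without BN-Lx male replicate 1 only a bound is left, at least 1930-fold. The log2 fold change was 12.34 without BN-Lx male replicate 2, 12.44 without SHR male replicate 1 and 13.87 without SHR male replicate 2. ENSRNOG00000056398 had 16.6 ± 1.8 CPM in SHR males and no count in either BN-Lx male, at least 264-fold higher (adjusted p = 2.7e-06). ENSRNOG00000057971 had 30.7 ± 28.1 CPM and ENSRNOG00000000490 had 21.2 ± 2.65 CPM in BN-Lx males, and neither had a count in SHR males. These are at least 171-fold (adjusted p = 9.1e-05) and at least 306-fold lower (adjusted p = 0.0086). The bound of ENSRNOG00000057971 was 803-fold without BN-Lx male replicate 2. The call of ENSRNOG00000000490 was lost without SHR male replicate 1 (adjusted p = 0.15) or 2 (adjusted p = 0.16). That of ENSRNOG00000057971 was lost in the fit of the 4 males alone (adjusted p = 0.48) and with limma (adjusted p = 0.12). Both were lost with b35 libraries alone (adjusted p = 0.35 and 0.064).

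Of the 1724 genes called in females, 1572 (91.2%) had the same direction in males, against 52.5% of the genes not called. Across the called genes, which are not independent replicates, the female and male log2 fold changes had Pearson's r of 0.907 and Spearman's rho of 0.891, with a slope of 0.977. The slope rests most on the genes with the largest changes. The median ratio of the male to the female log2 fold change was 0.883. The count in males depended on single animals. Leaving out any of the 4 males gave 61 to 74 called genes, with the lone male of that strain assumed to vary like the other groups. DESeq2 called 316, of which 144 were among the 145. The fit of the 4 males alone called 56, of which 34 were among the 145, and the b35 libraries alone, with a lone SHR male, gave 55.

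**Figure D3:**
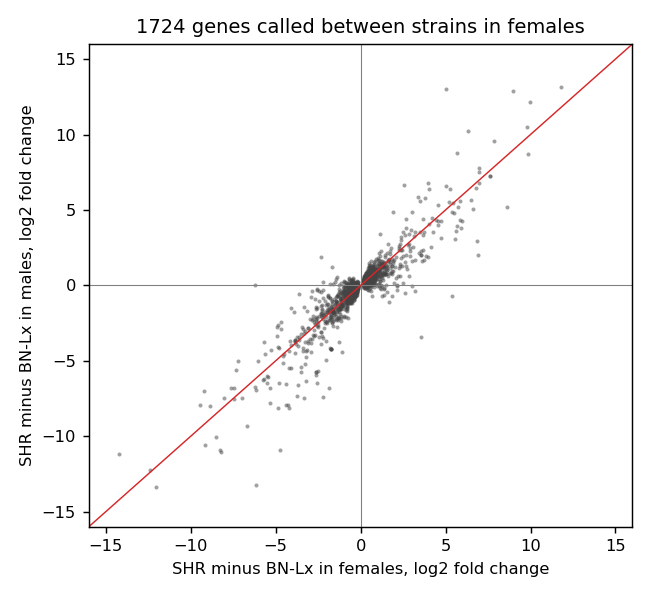
Strain difference of each of the 1724 genes called in females, as log2 fold change of SHR over BN-Lx in females (x axis) and in males (y axis), with a red line of equal change. Of these genes, 1572 lie on the same side of 0 in both sexes.

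The sex comparison called 6 genes in BN-Lx and 6 in SHR, and they were the same 6 genes. The other genes did not pass the threshold in either strain. Of the 6, 5 were present in males and close to absent in females, and ENSRNOG00000051257 was present in females and low in males. ENSRNOG00000060496 had 35.7 ± 5.76 CPM in BN-Lx males (SD, n = 2) and 0.00186 ± 0.00644 CPM in BN-Lx females (n = 12), a log2 fold change of 13.31 ± 0.58 (SE, adjusted p = 2e-08). ENSRNOG00000060048 had 21 ± 4.09 and 0.00372 ± 0.0129 CPM there, a log2 fold change of 11.93 ± 0.66 (SE, adjusted p = 2e-08). Of the BN-Lx females, only pre-estrus replicate 3 had counts of these genes, 1 and 2. Without it the changes are bounds, at least 411-fold and at least 234-fold (adjusted p = 2.7e-06 and 9.3e-07). In SHR, ENSRNOG00000057231 had 80.8 ± 3.27 CPM in males and 0.0388 ± 0.0862 CPM in females, a log2 fold change of 12.15 ± 0.62 (SE, adjusted p = 2.3e-10). ENSRNOG00000060617 had 30.7 ± 0.748 and 0.00776 ± 0.0161 CPM, a log2 fold change of 12.14 ± 0.47 (SE, adjusted p = 1e-10). For ENSRNOG00000057231 it was 11.06 without SHR male replicate 1 and 13.87 without SHR male replicate 2, and for ENSRNOG00000060617 it was 12.83 without SHR male replicate 2 and 13.01 without SHR post-estrus replicate 8. ENSRNOG00000051257 had 20.3 ± 3.34 CPM in BN-Lx females and 0.296 ± 0.036 in BN-Lx males, a log2 fold change of -6.07 ± 0.53 (SE, adjusted p = 2.6e-07). Its log2 fold change in SHR was -6.78 ± 0.57 (SE, adjusted p = 1.1e-07), from 17 and 0 counts in the males. It was -5.7 without SHR male replicate 2, and without SHR male replicate 1 the change is a bound of at least 209-fold. The remaining male-high gene had 257 to 279 counts in the 4 males and no count in any of the 24 females.

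These 6 genes sorted all 28 libraries by the labelled sex. They were selected by those labels and matched to no gene name, so this is not an independent check of the labels. Apart from the male-high gene with no female count, the male-high genes had 997 to 4089 counts in each male and at most 21 in each female, and ENSRNOG00000051257 had 727 to 1495 counts in each female and at most 19 in each male. No gene was called for a sex difference that differed between the strains, with 632 genes at an unadjusted p under 0.05, 3 called by DESeq2 and 0 by limma. The precision of this test is given with the other interactions below. Without SHR male replicate 2, the sex comparison in SHR called 23 genes and the sex by strain comparison called 6, with 981 genes at an unadjusted p under 0.05. That count was 289 without SHR male replicate 1, 206 without BN-Lx male replicate 1 and 1371 without BN-Lx estrus replicate 9. The b35 libraries alone gave 77 genes for sex in BN-Lx and 6 in SHR. Both BN-Lx males carried the suffix b35, so b37 gave no value there, and b37 alone gave 6 in SHR. In SHR each of these tests has a lone male, assumed to vary like the other groups. DESeq2 called 7 genes in BN-Lx, of which 3 were among the 6, and 17 in SHR, of which 5 were. With the number in the sample description as a block, 1 gene was called in BN-Lx and 2 in SHR, and 1 in each strain was among the 6. The fit then had 12 residual degrees of freedom in place of 19. In SHR the log2 fold change of ENSRNOG00000057231 was 12.41 ± 2.97 and that of ENSRNOG00000060617 was 14.47 ± 2.9 (SE), so the folds stayed large and the calls were lost with the larger errors. In BN-Lx the calls of ENSRNOG00000060496 and ENSRNOG00000060048 were lost at log2 fold changes of 11.73 and 10.24. Their deviance was the same with and without the sex contrast (2.09 and 12.8), so that block test carried no information on them.

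**Figure D4:**
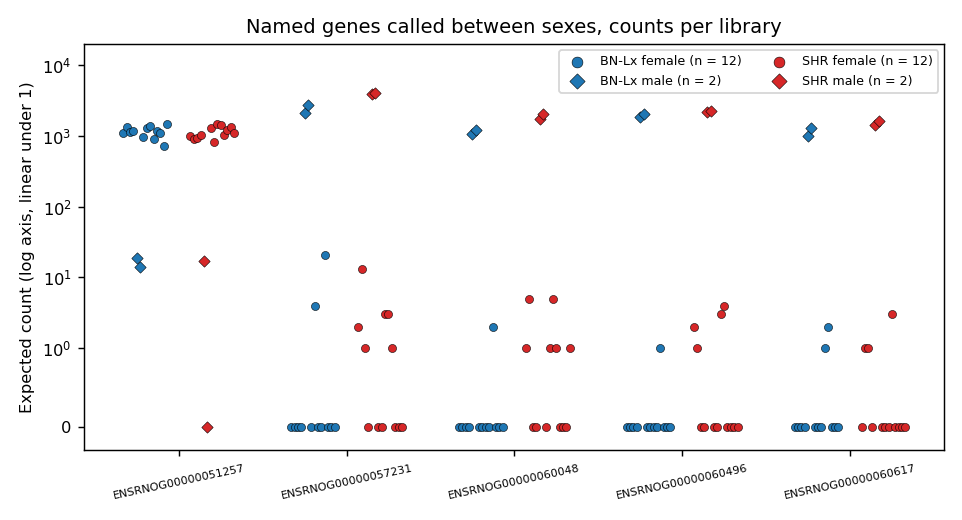
Expected counts (y axis, logarithmic above 1 and linear below) of the genes named between sexes (x axis) in each library, with diamonds for males, circles for females and colour for strain. ENSRNOG00000051257 lies at 727 or above in all females and at 19 or below in all males, and the other genes show the reverse.

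The stage comparisons asked which genes change over the estrous cycle in each strain. No gene was called by edgeR in any of them in the fit of all 28 libraries. In fits of only the libraries compared, edgeR called 1 gene for any stage difference in BN-Lx, 2 for estrus against pre-estrus in SHR and 0 in the other stage tests. In BN-Lx, the test of any difference among the 3 stages (n = 4 each) had 589 genes at an unadjusted p under 0.05, a smallest adjusted p of 0.977, 3 genes called by DESeq2 and 0 by limma. Estrus against pre-estrus had 672 genes at an unadjusted p under 0.05, with 6 called by DESeq2 and 0 by limma. Post-estrus against estrus had 357, with 5 and 0. Post-estrus against pre-estrus had 912, with 4 and 0, and its smallest adjusted p of 0.512 was the lowest of the stage tests. Single libraries moved these counts, with 0 genes called in each case. Without BN-Lx estrus replicate 2 they were 1867 for any stage difference, 3019 for estrus against pre-estrus and 1652 for post-estrus against estrus. Any stage difference had 942 without BN-Lx post-estrus replicate 6. Estrus against pre-estrus had 433 without BN-Lx estrus replicate 9 and 1032 without BN-Lx pre-estrus replicate 5. Post-estrus against estrus had 233 without BN-Lx estrus replicate 8, 705 without BN-Lx post-estrus replicate 3, 756 without replicate 4 and 125 without replicate 5 of that stage. Post-estrus against pre-estrus had 1584 without BN-Lx post-estrus replicate 6.

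These comparisons limit how large a general change could be, as far as the error shared by all groups holds for BN-Lx. Among 14050 genes with a mean of at least 1 CPM, the 95% interval of the change lay within 2-fold in either direction for 87.1% of genes in estrus against pre-estrus in BN-Lx, 89.5% in post-estrus against estrus and 88.8% in post-estrus against pre-estrus. It lay within 4-fold for 98.1%, 98.1% and 97.9%. The error was estimated over both strains, and female animals may vary more in BN-Lx (below). The BN-Lx intervals may thus be too narrow.

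The libraries with suffix b35, fitted without the others, called in BN-Lx 2919 genes for any stage difference, 2182 for estrus against pre-estrus, 2410 for post-estrus against estrus and 425 for post-estrus against pre-estrus, while b37 libraries alone called 0 in each. The b35 set held 5 BN-Lx females, with a lone post-estrus animal assumed to vary like the other groups, so the tests with post-estrus rest on 1 animal there. In it the most abundant gene took 33.7% and 34.7% of gene counts in the pre-estrus libraries, 35.9% in the post-estrus library, and 22.3% and 19.7% in the estrus libraries.

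In SHR, the test of any stage difference had 116 genes at an unadjusted p under 0.05, a smallest adjusted p of 1, 5 genes called by DESeq2 and 1 by limma. Estrus against pre-estrus had 162, with 8 called by DESeq2 and 1 by limma. Post-estrus against estrus had 194, with 8 and 0, and post-estrus against pre-estrus had 96, with 4 and 1. Estrus against pre-estrus had 96 without SHR pre-estrus replicate 10 and 335 without SHR pre-estrus replicate 12. Post-estrus against estrus had 351 without SHR post-estrus replicate 6, and post-estrus against pre-estrus had 148 without SHR post-estrus replicate 8. The 95% interval lay within 2-fold for 90.1%, 88.4% and 92.3% of the 14050 genes, in the same order. The 116 genes for any stage difference were 0.64% of the 18134 tested, where a share of 0.05 is expected without any difference. Other splits of the SHR females had a median of 200 such genes. The error was estimated over both strains, and animals may vary less in SHR (below). The SHR stage tests and intervals may thus be too cautious. With b35 libraries alone, 0 genes were called in each SHR stage test. With b37 libraries alone, where SHR post-estrus had a lone library assumed to vary likewise, 1 gene was called for any stage difference, 0 for estrus against pre-estrus, and 1 each for post-estrus against estrus and against pre-estrus.

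The interaction of sex and cycle with strain was the question of the study's design. A lack of calls in its tests does not show that interactions are absent. For sex by strain, the median standard error was 0.279 on the log2 scale. The interval of the change lay within 2-fold for 60.4% of the 14050 genes. In the stage pairs these values were 0.177 to 0.178 and 87.1% to 92.3%. The tests below cover several contrasts at once and had no such interval. No interaction was included in the simulation. No gene was called by edgeR for stage differences that differed between the strains, with 268 genes at an unadjusted p under 0.05, a smallest adjusted p of 0.972, and 1 gene called by DESeq2 and 1 by limma. The test over the 3 female stages and males together also called 0, with 276 genes at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma. The b35 libraries alone called 5654 and 3834 genes in these tests, with the same 5 BN-Lx females as above, and b37 libraries alone called 1 in the former and could not give the latter, having no BN-Lx male. Without BN-Lx estrus replicate 9, 1 gene was called in each. Without BN-Lx estrus replicate 2 the counts at an unadjusted p under 0.05 were 915 and 1003, and without SHR male replicate 2 the latter was 437.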

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

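The tests of other splits, of reads lost against a reference, of RNA shares on the strain calls, of spike-in ratios, of depth and of the axis against RNA shares by correlation were chosen after the result was seen. The RNA shares as covariates in the BN-Lx split and the spike-in set as a term were chosen after seeing the data, but before their own result was seen.

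In 57 sets of 4 libraries, 3 held a library far from the rest of its group, where chance flags about 1 in 20 sets. ENSRNOG00000057971, a short gene of 116 bases, stood at 4.19 CPM in BN-Lx estrus replicate 4 against 31.3 to 33.5 CPM in the other estrus libraries. It stood at 74 CPM in BN-Lx post-estrus replicate 5 against 26.7 to 34.6 CPM. SHR pre-estrus replicate 10 held 4.35% spike-in counts against 3.18% to 3.34%.

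The spike-in RNAs, which the comparisons do not use, took a median of 3.26% of counts. Their profiles fell into 2 sets of 16 and 12 libraries, with the first component of 37 well-measured spike-ins holding 94.3% of their variance. Between the sets, 8 spike-ins differed by a mean of 1.96 on the log2 scale, 9 by -0.0587, 10 by -0.63 and 10 by -1.02. A candidate explanation is that 2 spike-in mixes with 4 fixed ratios were used. All 37 lay within 0.15 of the ratios 4, 1, 0.667 and 0.5, which cover 30.6% of the observed range. A library batch that also alters gene expression is argued against, since the spike-in set as a term called 0 genes. The labels do not name a mix, and no biological explanation was tested.

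For the genes called between strains in females, chance placement of single animals is argued against as the only source. Of 100 splits of the females within stage, only 1, the real one, gave 1724 calls, and the highest other gave 0. By genes at an unadjusted p under 0.05, 12 of the 100 splits had as many (real 3735, highest other 5882). That count alone would not argue against chance. Except for the real one, the splits mix the strains, so strain differences enter their error and can lower their calls. Within BN-Lx alone, a split that mixed the stages called 5783 genes. The splits of both strains thus do not show how many of the 1724 calls chance could give. The splits cannot tell strain from the number in the sample description, as no number occurs in both strains. Loss of SHR reads against a reference from the BN strain could lower genes in SHR but raise them only by the shift of scaling, and the reference is not given in the sources used here. It would not give the 113 genes called over 4-fold higher in SHR, a size beyond the scaling factors (0.85 to 1.14), though reads passed to related genes were not tested. For the 1446 called genes under 4-fold it stays open, since 50.4% were lower in SHR and scaling centres the folds, and likewise for the 165 over 4-fold lower. A different share of the most abundant RNAs is also argued against as the whole cause, since 1217 of the 1724 genes were called again with the shares as covariates, and the difference between the strains themselves stays open as a hypothesis.

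Libraries of a group differed along an axis, the first component of the residuals, which held 24.8% of the residual variance. It followed the share of the most abundant gene, with group and suffix means removed (r = -0.962, permutation p = 1e-05, the smallest possible, adjusted over 5 measures 2.5e-05, rho = -0.955, p = 1e-05, adjusted 5e-05, n = 28). The 2 abundant gene rows with identical counts moved the other way (r = 0.893, p = 1e-05, adjusted 2.5e-05, rho = 0.861). Without the 2 farthest libraries r for the most abundant gene was -0.955, within b35 -0.957 and within b37 -0.967. A BN-Lx split that mixed the stages called 5783 genes, and 0 remained with the shares of the most abundant RNAs as covariates, though the split itself parted libraries by that share (34.6% against 25.8% and 25.4%) and its last set held no pre-estrus library. This is consistent with the shares of these RNAs moving with the axis, in opposite directions, and does not say which drives which. Sequencing depth stays open (r = 0.413, permutation p = 0.117, adjusted 0.146, rho = 0.423, p = 0.0736, adjusted 0.123, without the 2 farthest 0.346, b35 0.31, b37 0.52), and no biological explanation was tested.

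For the stage comparisons chance was not excluded, judged by genes at an unadjusted p under 0.05 in other splits of the libraries. In BN-Lx, 72 of 100 splits had as many for any stage difference (real 589, highest other 8134). For estrus against pre-estrus it was 14 of 35 (672, 5843), for post-estrus against estrus 31 of 35 (357, 6853) and for post-estrus against pre-estrus 18 of 35 (912, 7047). In SHR it was 84 of 100 for any stage difference (116, 2120). The pairs gave 28 of 35 for estrus against pre-estrus (162, 3769), 25 of 35 for post-estrus against estrus (194, 4248) and 34 of 35 for post-estrus against pre-estrus (96, 4570). For stage by strain it was 83 of 100 (268, 5298). These ranks depend on BN-Lx estrus replicate 2, without which they were 18 of 100 for any stage difference in BN-Lx, 2 of 35 for estrus against pre-estrus (3019, 3445), 9 of 35 for post-estrus against estrus (1652, 4898) and 33 of 100 for stage by strain (915, 6847). With all libraries, the highest other splits gave several times the real count. Without BN-Lx estrus replicate 2 this did not hold for estrus against pre-estrus (3019 against 3445). The BN-Lx split of 5783 calls parted libraries along the axis above.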

How the results depend on the processing

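Limma voom with quality weights (called limma from here on), 3 surrogate variables, RNA shares as covariates, the spike-in set as a term, leaving out 3 outlying libraries, fitting each suffix alone and leaving out the 8 most abundant genes were chosen after seeing the data. The strain count in females stayed within 1.5 times of 1724 in all of them and in the alternatives set before the data were examined, except b37 alone (478), where the cause was not tested. Leaving out single libraries gave 1472 to 1840. The count in males moved from 145 to 316 with DESeq2, 56 with only the libraries compared, 745 with limma, 237 with surrogate variables, 471 with RNA shares, 224 without the 3 outlying libraries, 55 with b35 alone, and 61 to 74 without single males. Sex calls in BN-Lx were 11 with limma, 10 with RNA shares, 77 with b35 alone and 1 with the description number as a block, and 5 to 7 without single libraries. In SHR they were 17 with DESeq2, 13 with limma, 2 with that block and 5 to 23 without single libraries, the highest without SHR male replicate 2. Sex by strain, 0 as reported, gave 3 with DESeq2, 3 with b35 alone, 1 with that block and 0 to 6 without single libraries. The cause of these moves was not tested.

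DESeq2 called 3 genes for any stage difference in BN-Lx, 6 for estrus against pre-estrus, 5 for post-estrus against estrus and 4 for post-estrus against pre-estrus. In SHR it called 5, 8, 8 and 4, and it called 1 for each stage interaction. Only the libraries compared gave 1 for any stage difference in BN-Lx and 2 for estrus against pre-estrus in SHR. Limma gave 1 for any stage difference in SHR, 1 for estrus against pre-estrus, 1 for post-estrus against pre-estrus and 1 for stage by strain. With b35 alone, BN-Lx gave 2919, 2182, 2410 and 425, stage by strain 5654 and the sex and stage group interaction 3834. With b37 alone, SHR gave 1 for any stage difference, 1 for post-estrus against estrus and 1 against pre-estrus, and stage by strain gave 1. Without BN-Lx estrus replicate 9, stage by strain and the group interaction gave 1 each, within a range of 0 to 1 without single libraries. The other stage tests gave 0 without any single library.

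Same-numbered libraries were taken to come from different animals, since whole brains were used, and their deviations from the group means correlated at a mean of -0.134 over 9 pairs, so the numbers did not pair them. With a replicate block, post-estrus against pre-estrus called 24 genes in BN-Lx and 0 in SHR, and strain in males called 132, of which 65 were among the 145. Strain differences cannot be estimated with the description number as a block, as no number occurs in both strains. The 6 gene-list tests were not run, because 0 of 646 entries matched. Named genes kept their direction in all alternatives run that carried information on them. With the description number as a block in BN-Lx, ENSRNOG00000051257 had a log2 fold change of -6.16. That block carried no information on ENSRNOG00000060496 and ENSRNOG00000060048. Low counts limit part of the genes, with a median standard error of the female strain difference of 0.44 under 1 CPM against 0.079 over 64 CPM.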

Other observations

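The test of the spread between animals was set before its result was seen, but after the libraries' positions on the residual axis were known. The spread between animals of the same stage may be larger in BN-Lx than in SHR. The mean squared deviation per library from its group mean in log2 CPM was 0.347 ± 0.18 in BN-Lx females and 0.206 ± 0.0717 in SHR females (SD, n = 12 each, permutation p = 0.00683), a ratio of 1.69. The ratio was 1.5 with the values of 3 libraries far out on the residual axis left out. These were BN-Lx estrus replicate 2, BN-Lx post-estrus replicate 5 and SHR post-estrus replicate 13. The group means still included them, which can enlarge the deviations of the other libraries in their groups. The males showed no larger spread in BN-Lx, with 0.106 per library against 0.119 in SHR (n = 2 each). Libraries of a group share a mean, so the values are not fully independent.

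Of 24 females, 11 had at least 1 count of the 5 genes found in males. The highest totals were 26 counts in BN-Lx pre-estrus replicate 3, 0.307% of the mean of the males, and 20 in SHR estrus replicate 5, 0.236%. The median female had 0.

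The suffix term called 10 genes, 2 of them higher in b37, with 1459 genes at an unadjusted p under 0.05. The spike-in sets did not follow the suffix (Fisher's exact p = 1), the group (exact p = 0.933) or the number in the description (exact p = 0.916).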
